A study of Bos taurus with 24 samples.

How the data were processed

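The libraries were made, per the labels, from flash-frozen membranes by extraction with a column kit or a phenol reagent, selection of polyadenylated RNA and sequencing on 1 instrument type. All 24 libraries carry the same protocol text. Per the labels, the authors checked reads with FastQC, aligned them with HISAT2 to the cattle genome ARS-UCD1.2, counted them per gene with featureCounts and tested pairs of groups with edgeR, with no versions stated. Each of the 8 deposited tables used here holds 3 libraries of 1 group and 3 of another, with Ensembl gene identifiers, and genes under an unstated limit had been removed. The other 25 deposited sheets repeat parts of these tables and were not used. Of 48 table columns of values, 0 belonged to no sample.

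The deposited values of 6 tables are a normalised signal, in CPM of a scaled library size, and the authors rounded 6 of the columns to 2 decimals. Per the file headers and the values, the deposited tables of female against male IVP libraries are in RPKM, as reads per kilobase of the listed gene length and per scaled library size. The authors' deposited fold changes are on the log2 scale per the file headers, and the deposited p-value and its adjusted form come from their likelihood ratio test in edgeR. In the 42 unrounded columns every value was close to a whole multiple of 1 step. At least 99.99% of the values of each column were whole within 0.05 reads. The whole reads per gene were recovered from these steps, and 276192 of 276192 values found in more than 1 table were identical. The totals of recovered reads were 27578743 to 88402468 per library. No 2 replicates of a group were copies, since the chi-square per gene over the 24 pairs within groups was at least 70.4. The tables listed 18284 genes, of which 15093 had a symbol in the tables.

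The groups follow the titles, the characteristics and the table columns. The description text gave another day than the title for 6 samples and another method for 2 of the samples. The titles also hold an R number whose meaning is not stated. It was 1 or 2 in the AI libraries, 3 in the IVP day 18 libraries and 4 in the IVP day 32 libraries, so no comparison of methods could be told apart from it. The plan fixed before the data were examined assumed read counts and named edgeR. Because the deposited unit was a normalised signal or RPKM, the plan's rule for such values applied. The values were moved to log2 with 1 added, genes at 1 or more in at least 3 libraries were kept, and groups were compared with limma 3.58.1 in R 4.3.3 with a trend in the prior variance and robust moderation. P-values were adjusted by the Benjamini-Hochberg procedure and genes under 0.05 were called. Each method and sex comparison used its own 6 libraries. The interactions used the 12 libraries of a day, with the female and male method tables set side by side and a mean per group. The day comparisons used the 12 libraries of a sex, as the recovered reads in CPM after TMM scaling, because no table holds both days.

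The plan fixed 35 gene lists beforehand, and lists with at least 5 tested members entered camera in limma on the log2 values, at a preset correlation of 0.01. This replaced the planned voom values, which need counts. An estimated correlation and the rotation test fry were run beside it. Up to 8 genes per direction with the largest called changes were named in the sex, day and interaction comparisons and up to 12 in the method comparisons, if they had a symbol and at least 5 CPM in the higher group. From each described list up to 4 members with the smallest p were eligible too. Because limma called few genes between methods, the same naming rule was applied to genes that DESeq2 called. To be named, these also had to be called in the authors' deposited table of the same libraries. This naming was chosen after the counts were seen.

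Alternatives were a pseudocount of 0.1, no filter, a filter at 5, no robust moderation, each replicate left out in turn, all 12 libraries of a day in 1 fit and, in the AI sex comparisons, the R number as a covariate. On the recovered reads, the quasi-likelihood test of edgeR 4.0.16 with TMM or RLE factors and the Wald test of DESeq2 1.42.0 were run as well. For genes whose reads were recovered, these tests called 0 to 10024 genes with edgeR and RLE factors and 4 to 10379 with DESeq2 over the 12 comparisons. Added later was a fit on values from which a smooth trend on gene length (span 0.5) had been removed per library. Females were also fitted between days without both doubted IVP libraries, day 18 replicate 1 and day 32 replicate 1. Also added later were the DESeq2 test of females on day 32 without IVP replicate 1 and the medians of called lists with each library left out. All 10 splits of each set of 6 libraries were tested, and 100 drawn splits for fits of 12 libraries.

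The pipeline was tested on simulated data with 3 libraries per group and 200 changed genes. In data modelled on females on day 18, limma called 5 of 66 genes changed 2-fold, 46 of 67 changed 4-fold and 53 of 67 changed 8-fold, and 18 unchanged genes. In data modelled on males on day 32, it called 16 of 73, 35 of 55 and 60 of 72, and 10 unchanged genes. DESeq2 called 45 and 66 unchanged genes in the same data, so its counts are more liberal than those of limma. With no gene changed, limma called 2 and 0 genes and DESeq2 called 8 and 18. In each simulation camera called the single list that had been shifted and 0 others. The simulated genes were drawn independently, so this cannot show how camera behaves on lists of correlated genes. In females on day 18 the estimated correlation was 0.939 for mitochondrially encoded and 0.641 for ribosomal protein genes. Removal of the length trend brought a simulated Spearman correlation of length and change from 0.671 to -0.025 and from 0.793 to -0.013.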

Results

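Gene expression was measured by sequencing of RNA from bovine extraembryonic membranes, as a piece of the conceptus on day 18 of pregnancy and a piece of chorioallantois on day 32. The pregnancies came from artificial insemination (AI) or from embryos produced in vitro (IVP). The 24 libraries fell into 8 groups of 3, one for each combination of sex, method and day. The tables held between 27578743 and 88402468 recovered reads per library, and 13749 genes had reads recovered for all 24 libraries. Nothing in the labels says that the replicates of a group came from separate animals, so every p-value here measures the spread between samples. A gene was called when its adjusted p in limma was under 0.05, and all values with an SD are group means with n = 3. CPM is the reads of a gene per recovered reads of its library, in the usual unit of that name, and scaled CPM is the same over a scaled library size.

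Female and male libraries differed in composition in every group. Mitochondrially encoded genes took 8.58% to 65.2% of the reads in female libraries and 0.910% to 2.11% in male libraries. The highest share was in female IVP day 18 replicate 1. The mean gene length weighted by reads was 1574 to 2861 bp in the female libraries and 3311 to 4061 bp in the male ones. In a principal component analysis of the 13749 genes, the first component held 44.6% of the variance and the second held 32.0%, and the libraries parted by sex and by day.

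**Figure D1:**
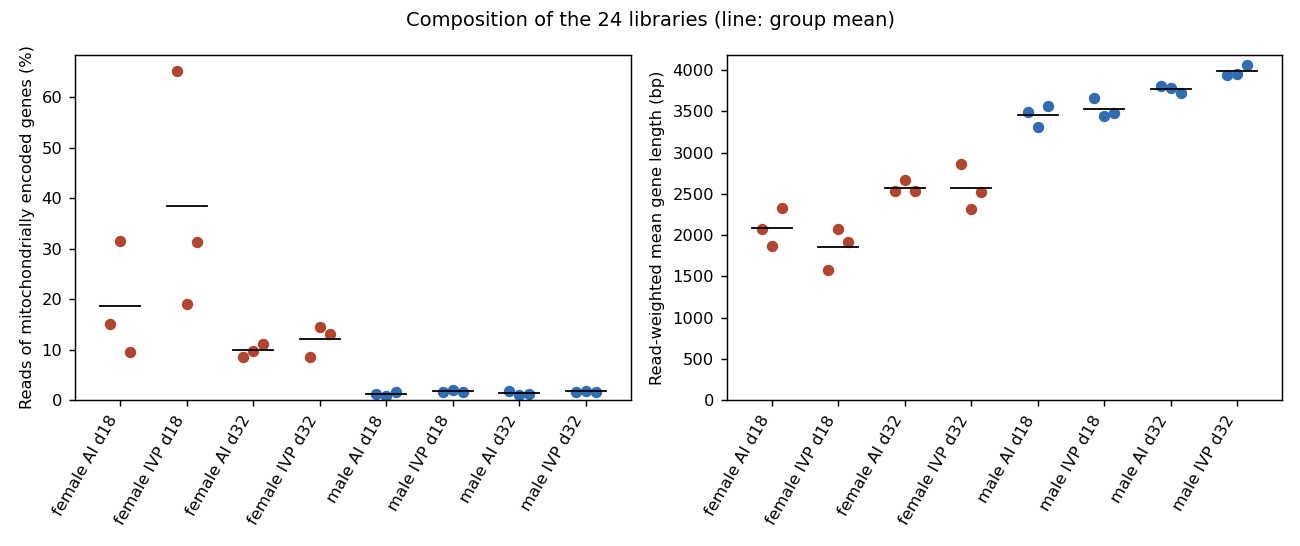
Share of reads from mitochondrially encoded genes (left, percent) and mean gene length weighted by reads (right, bp), with a point for each of the 24 libraries and a line for each group mean. Male libraries lay at 2.11% or less and at 3311 bp or more, and female libraries at 8.58% or more and at 2861 bp or less.

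Interferon tau, the signal by which the ruminant conceptus announces itself to its mother, and X-linked genes with a Y homologue were read in every group as checks of the labels. IFNT reached 661 ± 132 CPM in female AI day 18 libraries and 472 ± 613 CPM in female IVP day 18 libraries, where replicate 2 had 1179 CPM and replicates 1 and 3 had 134.5 and 101 CPM. In males on day 18 it reached 2149 ± 575 CPM after AI and 3543 ± 1400 CPM after IVP. IFNT2 averaged between 215 and 1178 CPM over the 4 day 18 groups and IFN-TAU at most 2.28 CPM. IFNT3 averaged between 650.3 and 2256 CPM. In female IVP day 18 replicate 2, IFNT2 had 568 and IFNT3 1601 CPM, against at most 47.9 and 175 CPM in replicates 1 and 3. The day 32 tables did not list these genes. CSH2, a placental lactogen, averaged 812 ± 125 and 682 ± 596 CPM in the female AI and IVP groups on day 32, and 219 ± 71.5 and 208 ± 69.8 CPM in the corresponding male groups. Female IVP day 32 replicate 1 had 15.1 CPM of it. Its mean was at most 3.12 CPM in each day 18 group.

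XIST was not among the genes of the tables. The 16 X-linked genes with a Y homologue had medians below 0 for female minus male in all 4 sex comparisons. These were -0.89 and -0.51 after AI on days 18 and 32, and -0.69 and -0.64 after IVP. With a trend on gene length removed they were -0.26, -0.27, -0.12 and -0.08. Of the 16 genes, 4, 5, 4 and 4 were called higher in females and 8, 9, 8 and 7 higher in males in these comparisons. KDM5C had 65.5 ± 9.73 CPM in female and 106 ± 18.9 CPM in male AI day 18 libraries, and 115 ± 9.38 against 107 ± 5.87 CPM in the AI day 32 libraries. In the IVP groups it had 55.0 ± 16.5 CPM in females and 116 ± 28.1 CPM in males on day 18, and 110 ± 20.1 against 125 ± 8.58 CPM on day 32. No Y-linked homologue appeared by symbol among the genes of these checks, so none was analysed here. Whether reads of Y homologues were counted under the X-linked genes was not tested. These X-linked values therefore cannot check the sex labels.

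The first question was how IVP conceptuses of 1 sex and day differed from AI conceptuses. The libraries of the 2 methods also differed in the R number of their titles, whose meaning is not stated, so the comparisons cannot part method from it. In females on day 18, limma tested 11123 genes and called 1, while 849 had an unadjusted p under 0.05. The latter count ran from 307 without AI replicate 3 to 2579 without IVP replicate 2, with 544 without AI replicate 1 and 448 without IVP replicate 1. The called gene was listed as COX7C, the symbol of a subunit of cytochrome c oxidase, with a length of 177 bp. It was lower after IVP, at 0.90 ± 0.547 scaled CPM against 19.4 ± 5.44 after AI, a log2 change of -3.43 with an adjusted p of 0.0160. The groups did not overlap for 1331 genes (11.97%), where chance gives 10% on average over the 10 splits of 6 libraries. Because genes vary together, 1 split can lie away from that average, and other splits were not counted. These shares, here and below, therefore do not measure an excess over chance. No gene was called without AI replicate 1, IVP replicate 1 or IVP replicate 2, and 4 were called without IVP replicate 3. The log2 change of COX7C lay between -3.65 and -3.24 with any 1 library left out. Its call was lost, at an adjusted p of 0.325, when all 12 libraries of the day were fitted together. The quasi-likelihood test of edgeR on the recovered reads called 0 genes and DESeq2 called 75.

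DESeq2 called other genes in females on day 18. The apolipoprotein gene APOA2 averaged 52.2 ± 10.9 CPM after IVP and 17.7 ± 9.16 CPM after AI, and its adjusted p was 0.0143 in DESeq2 and 0.586 in limma. APOB had a log2 change of 2.08, ALDOB of 2.65 and the complement component C8G of 2.93. The fetal growth factor IGF2 had a DESeq2 change of 2.47, with 32.8 ± 18.2 against 10.3 ± 6.58 CPM. On the lower side, the membrane mucin MUC15 had 1.19 ± 0.688 CPM after IVP and 13.3 ± 6.18 CPM after AI. Of the 75 genes that DESeq2 called, 49 were also called in the authors' deposited table, which rests on the same 6 libraries.

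Gene lists fixed beforehand were tested with camera at its preset correlation between genes. In females on day 18, the 21 endoderm and yolk sac genes had a median of 0.46 above AI, with an adjusted p of 7.13e-06. None was called over all genes, and 5 were higher when adjusted over the list alone. The transcription factor GATA4 averaged 21.5 ± 8.98 scaled CPM after IVP and 6.38 ± 1.90 after AI. The call was lost at an adjusted p = 0.210 with an estimated correlation. The 27 extracellular matrix genes had a median of 0.43, with 0 called over all genes and 3 higher when adjusted over the list alone. Their adjusted p was 4.65e-05 at the preset correlation, and adjusted p = 0.718 with an estimated correlation. Transcripts of the 13 mitochondrially encoded genes had a median of 1.491, with 0 called over all genes and 0 when adjusted over the list alone. Their adjusted p of 7.13e-06 became adjusted p = 0.718 with an estimated correlation. The mitochondrial median was 0.65 without IVP replicate 1, whose share of mitochondrial reads was 65.2%, and 2.30 without IVP replicate 2. Without IVP replicate 1 the endoderm median was 0.85 and the extracellular matrix median 0.69, and the latter was 0.28 without AI replicate 2.

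In females on day 32, limma tested 12841 genes and called 0, with 621 at an unadjusted p under 0.05. That count was 1574 without IVP replicate 3, whose description named AI, and 1339 without IVP replicate 2. It was 174, 218 and 221 without AI replicates 1, 2 and 3. The edgeR test called 0 genes and DESeq2 called 72, or 115 without IVP replicate 1. The groups did not overlap for 17.5% of genes, where chance gives 10%. The genes that DESeq2 called higher after IVP included AHSG and FETUB, which encode fetuins, at log2 changes of 4.04 and 3.95. FETUB averaged 328 ± 282 CPM after IVP and 20.2 ± 7.12 CPM after AI. The calls of AHSG and FETUB were lost in DESeq2 without IVP replicate 1, at changes of 2.21 and 3.84 and adjusted p-values of 0.620 and 0.186. The erythroid genes KLF1 and AHSP had DESeq2 changes of 2.95 and 2.93, and 2.04 and 2.15 without that replicate, where both were called. Steroid 17-alpha-hydroxylase, CYP17A1, was lower in DESeq2, with 1.27 ± 0.505 CPM after IVP and 8.28 ± 3.42 CPM after AI and an adjusted p of 9.22e-04. The adjusted p of these genes in limma was 0.600.

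IVP replicate 1 of the female day 32 group stood apart from the other 5 libraries. Its pregnancy-associated glycoproteins, which trophoblast secretes, had a median log2 difference of -6.93 from the other female day 32 libraries. Its endoderm genes were higher by a median of 3.35, its erythroid genes by 3.28 and its mesenchyme genes by 2.96. With this library, the 20 pregnancy-associated glycoproteins had a median of -2.67 for IVP minus AI and the 21 erythroid genes 2.24. The 18 endoderm genes had a median of 1.76, the 24 cholesterol biosynthesis genes -0.74 and the 74 cytosolic ribosomal protein genes 0.52. PAG15 averaged 40.6 ± 40.7 scaled CPM after IVP and 240 ± 76.0 after AI. Without this library the medians were -0.44 for pregnancy-associated glycoproteins, 1.43 for erythroid, 0.95 for endoderm, -0.20 for cholesterol biosynthesis and 0.37 for ribosomal protein genes. The 5 lists had adjusted p-values of 1.75e-05, 6.25e-12, 5.23e-06, 7.65e-05 and 3.89e-18 in camera, with 0 members called over all genes and 0 when adjusted over the list alone. All 5 calls were lost, at an adjusted p = 0.731 with an estimated correlation. In all, camera called 15 of the lists. Without this library it called 11, of which 8 were among the 15, these 5 lists included.

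In males on day 18, limma tested 12004 genes and called 0, with 667 at an unadjusted p under 0.05, while edgeR called 0 and DESeq2 called 4. The unadjusted count was 410, 164 and 301 without AI replicates 1, 2 and 3, and 1978 without IVP replicate 2. It was 924 without IVP replicate 3, whose description named AI and day 32. The groups did not overlap for 17.5% of genes, where chance gives 10%. The metalloproteinase gene ADAM19 was the only DESeq2 call that met the naming rule. It had 14.3 ± 4.58 CPM after IVP and 41.5 ± 5.79 CPM after AI and a log2 change of -1.54. Ribosomal protein genes were lower after IVP in camera, where the 74 members had a median of -0.58 and an adjusted p of 2.45e-14. Without IVP replicate 1 that median was -0.28. RPS12 averaged 264 ± 131 scaled CPM after IVP and 781 ± 140.0 after AI. The 73 nuclear genes of oxidative phosphorylation had a median of -0.54, or -0.26 without IVP replicate 1, and an adjusted p of 1.67e-12. The 13 mitochondrially encoded genes lay on the other side of 0, with a median of 0.48 and an adjusted p of 0.00495. That call was lost without AI replicate 2 (0.249), where the median was 0.14, or without IVP replicate 2 (0.225). Of the members of the 3 lists, 0 were called over all genes and 0 when adjusted over the list alone. Each list had an adjusted p = 0.745 with an estimated correlation.

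The series title names male conceptuses on day 32, where limma tested 13811 genes and called 4, with 2665 at an unadjusted p under 0.05. The stricter filter gave 107 calls, 7 higher and 100 lower. With the main filter at 1, the 2665 genes at an unadjusted p under 0.05 became 1646 without AI replicate 1. They became 1768 without AI replicate 2 and 3559 without IVP replicate 1. The groups did not overlap for 3664 genes (26.5%), where chance gives 10%. PRUNE2 fell from 171 ± 46.0 scaled CPM after AI to 12.1 ± 1.88 after IVP, a log2 change of -3.69 with an adjusted p of 0.00683. The lysosomal transporter gene MFSD1 fell from 156 ± 8.45 to 58.5 ± 2.39 scaled CPM, with a log2 change of -1.40 and an adjusted p of 0.0216. Both calls were lost, at an adjusted p of 0.221, when all 12 libraries of the day were fitted together, where 1 gene was called higher and 0 lower. The other calls had no symbol: ENSBTAG00000053347 changed by -2.57 and ENSBTAG00000045530 by 2.05. No gene was called without AI replicate 1, IVP replicate 1 or IVP replicate 2. With AI replicate 2 or AI replicate 3 left out, 1 gene was called, and 5 were called without IVP replicate 3. The edgeR test called 2 genes and DESeq2 called 1285.

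**Figure D2:**
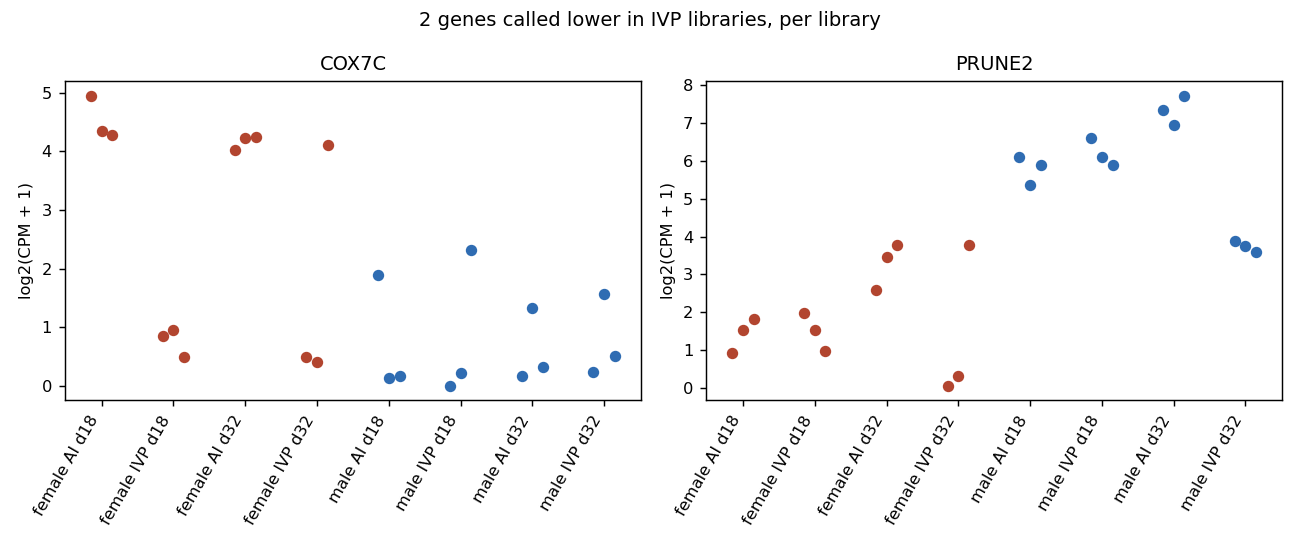
COX7C (left) and PRUNE2 (right) as log2(CPM + 1), with a point for each of the 24 libraries by group. COX7C was between 18.3 and 29.9 CPM in female AI day 18 libraries and at most 0.945 CPM in female IVP day 18 libraries, and PRUNE2 was at least 123 CPM in male AI day 32 libraries and at most 13.8 CPM in male IVP day 32 libraries.

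DESeq2 called more genes than limma in males on day 32. NLRC5, an activator of MHC class I genes, had 32.1 ± 23.4 CPM after IVP and 3.37 ± 1.18 CPM after AI. The Wnt antagonist SFRP5 had a change of 3.02 in DESeq2 and the homeobox gene HOXA6 of 2.59. On the lower side, the placental glycoprotein PAG19 averaged 43.4 ± 27.3 CPM after IVP and 171 ± 13.02 CPM after AI, with an adjusted p of 3.88e-04 in DESeq2 and 0.0752 in limma. Osteopontin, SPP1, had 234 ± 87.1 against 805 ± 386 CPM. The macrophage scavenger receptor MSR1 and complement C2 had changes of -2.14 and -2.04. The leukocyte gene list had a median of -0.65 in limma and was called lower by camera at its preset correlation. It was called in 3 of 6 fits with 1 library left out, and the call was lost with an estimated correlation. Of the 1285 genes that DESeq2 called, 733 were also called in the authors' deposited table. Among the 701 of these that limma tested, 701 had the same sign in limma. All these tests used the same 6 libraries, so neither count is independent support for the DESeq2 calls.

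In males on day 32, camera at its preset correlation called 8 lists lower after IVP and 3 higher. The 24 cholesterol biosynthesis genes had a median of -0.44 and an adjusted p of 1.36e-05. None was called over all genes, and 8 were lower when adjusted over the list alone. CYP51A1 averaged 94.1 ± 20.7 scaled CPM after IVP and 262 ± 67.0 after AI. EBP averaged 20.6 ± 1.30 against 44.3 ± 1.53. Among 31 genes of the unfolded protein response, 0 were called over all genes, while 12 were lower and 2 higher when adjusted over the list alone. Their median was -0.30 and their adjusted p 0.00115, and DNAJB9 had 58.4 ± 5.92 scaled CPM after IVP and 104 ± 7.09 after AI. The 74 ribosomal protein genes had a median of -0.39 and an adjusted p of 4.37e-10, with 0 called over all genes and 20 lower when adjusted over the list alone. These 3 lists lost the call, at an adjusted p = 0.621 with an estimated correlation.

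Lists of energy metabolism lay on both sides of 0 in males on day 32. The 13 mitochondrially encoded genes had a median of 0.44 and an adjusted p of 0.00527, with 0 called over all genes and 0 when adjusted over the list alone. Their call was lost at an adjusted p = 0.712 with an estimated correlation, and without AI replicate 2 (0.0759). Their median was 0.22 without AI replicate 2 and 0.66 without AI replicate 1. The 73 nuclear oxidative phosphorylation genes had a median of -0.22 and an adjusted p of 1.36e-05, with 0 called over all genes and 10 lower when adjusted over the list alone. That median was -0.36 without IVP replicate 1 and -0.13 without IVP replicate 3. SDHD averaged 47.6 ± 3.24 scaled CPM after IVP and 109 ± 12.7 after AI. That list had an adjusted p = 0.660 with an estimated correlation. Among 37 genes of fatty acid metabolism, 7 were lower when adjusted over the list alone and 0 over all genes, with an adjusted p of 0.0271, and 0.156 without IVP replicate 3. ACSL3 had 91.5 ± 8.09 scaled CPM after IVP and 190 ± 18.8 after AI. Among 23 glucose and amino acid transporters, 3 were lower when adjusted over the list alone and 0 over all genes, with an adjusted p of 0.0365. That call was lost without AI replicate 1 (0.0549), AI replicate 3 (0.128) or IVP replicate 1 (0.201). The 21 pregnancy-associated glycoproteins had a median of -0.51, or -0.77 without IVP replicate 1, with 5 lower when adjusted over the list alone, 0 over all genes and an adjusted p of 0.00103. Mesenchyme genes were higher, with a median of 0.76 over 25 members, 0.31 without IVP replicate 2, and an adjusted p of 7.65e-04. Their count was 0 over all genes and 0 when adjusted over the list alone. The last 4 lists also had an adjusted p = 0.621 with an estimated correlation.

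**Figure D3:**
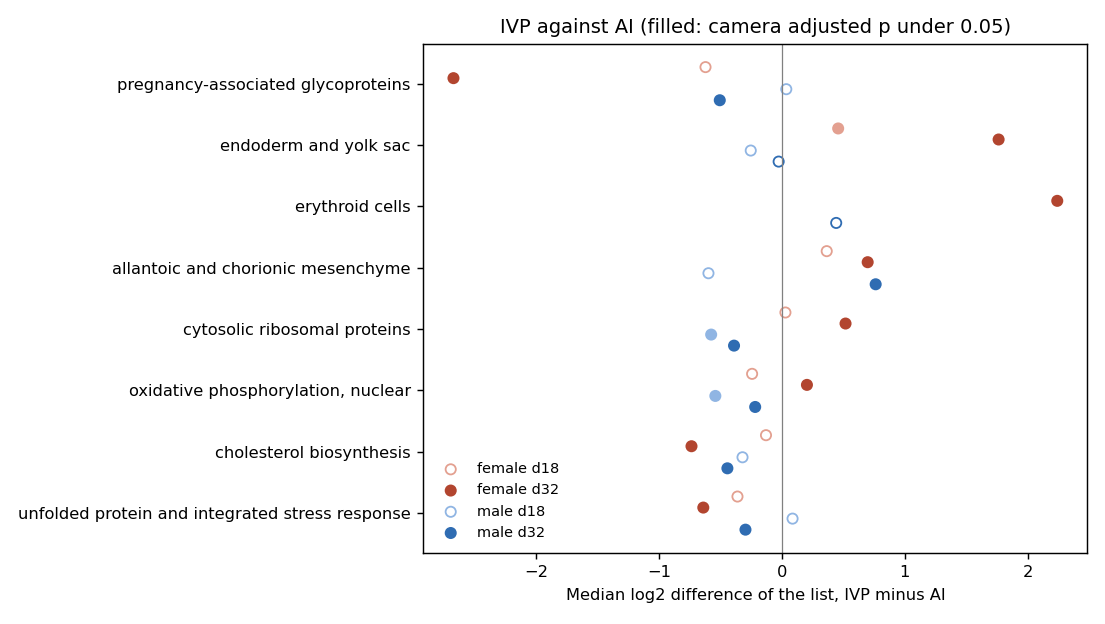
Median log2 difference of 8 gene lists, IVP minus AI, in each of the 4 method comparisons (filled points have a camera adjusted p under 0.05 at the preset correlation). Ribosomal protein genes had medians of -0.58 and -0.39 in males and 0.52 in females on day 32, and pregnancy-associated glycoproteins -2.67 in females on day 32, and -0.44 without IVP replicate 1.

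The next question was how the method effect differed between the sexes, tested as male IVP minus male AI less female IVP minus female AI. On day 18 limma tested 12297 genes and called 0, with 475 at an unadjusted p under 0.05 and a smallest adjusted p of 0.799. The unadjusted count was 876 without female IVP replicate 2, 720 without male IVP replicate 2 and 314 without female AI replicate 3. DESeq2 called 18 genes and edgeR called 0, and limma called 1 without male AI replicate 1. On day 32 limma tested 14036 genes and called 0, with 846 at an unadjusted p under 0.05 and a smallest adjusted p of 0.128. The unadjusted count was 1686 without female IVP replicate 3, 1406 without female IVP replicate 2, 550 without male AI replicate 2 and 552 without male IVP replicate 1. DESeq2 called 47 genes there and edgeR called 0.

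Endoderm genes had the day 18 list difference with the smallest adjusted p under an estimated correlation. The 20 genes had a median of -1.25, with 0 called over all genes and 2 lower when adjusted over the list alone. Their adjusted p was 1.69e-10 at the preset correlation, and the call was lost at an adjusted p = 0.0570 with an estimated correlation. APOA2 averaged 62.0 ± 19.2 scaled CPM in female IVP and 15.6 ± 8.30 in female AI libraries, against 0.822 ± 0.174 in male IVP and 3.29 ± 2.27 in male AI libraries. Ribosomal protein genes had medians of -0.64 on day 18, or -0.31 without male IVP replicate 1, and -0.87 on day 32 over 74 genes. The counts over all genes were 0 on both days, and 0 on day 18 and 37 on day 32 were lower when adjusted over the list alone. Their adjusted p-values in camera were 6.71e-16 and 2.12e-42. These calls were lost too, with an adjusted p = 0.532 with an estimated correlation on day 18 and an adjusted p = 0.617 with an estimated correlation on day 32. RPS27 averaged 60.4 ± 8.67 scaled CPM in male IVP and 139 ± 12.8 in male AI day 32 libraries, against 846 ± 178 in female IVP and 662 ± 96.7 in female AI libraries. The 21 erythroid genes had a median of -1.80 on day 32, with 0 called over all genes, 0 when adjusted over the list alone and an adjusted p of 9.97e-06. That call was lost at an adjusted p = 0.941 with an estimated correlation. Without female IVP day 32 replicate 1, camera called 6 lists, of which 3 were among the 9 called with it, and the erythroid median was -1.12. That median was -1.19 without male IVP replicate 1 and -2.75 without male IVP replicate 3. Without female IVP day 32 replicate 2 it called 19.

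Female and male conceptuses of the same method and day were compared next. After AI on day 18, limma called 7137 of 11770 genes, 3526 higher and 3611 lower in females. ND3, which is encoded in the mitochondrial genome, averaged 9483 ± 8451 scaled CPM in females and 99.8 ± 34.2 in males. Placental growth factor, PGF, had 103 ± 133 scaled CPM in females and 0.191 ± 0.137 in males, a log2 difference of 5.30 with an adjusted p of 0.00511. THY1 differed by 5.15. SRGN differed by 5.03, a call that was lost when all 12 libraries of the day were fitted together. Replication-dependent histone genes were the lowest in females, led by H2AC12 at 1.43 ± 2.05 against 299 ± 58.7 scaled CPM. The demethylase gene TET1 was at 17.7 ± 4.86 scaled CPM in females and 194 ± 6.86 in males.

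Of the 74 ribosomal protein genes, 72 were higher in females after AI on day 18, over all genes and when adjusted over the list alone. Their median was 2.25 and their adjusted p 1.84e-18. All 13 mitochondrially encoded genes were higher on both counts, with a median of 4.14 and an adjusted p of 1.30e-05. Of the 74 nuclear oxidative phosphorylation genes, 65 were higher and 2 lower over all genes, and 66 and 2 when adjusted over the list alone. All 8 tested pregnancy-associated glycoproteins were higher on both counts, with a median of 2.77 and an adjusted p of 0.0131. PAG8 averaged 1952 ± 294 scaled CPM in females and 216 ± 114 in males. Of 25 genes of DNA and histone methylation, 14 were lower and 2 higher over all genes and when adjusted over the list alone, with an adjusted p of 0.0131. These 5 lists had an adjusted p = 0.713 with an estimated correlation. Of 31 extracellular matrix genes, 16 were lower and 2 higher on both counts, with an adjusted p of 0.00259, and that call was lost at an adjusted p = 0.821 with an estimated correlation.

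After AI on day 32, limma called 9239 of 13391 genes, 4859 higher and 4380 lower in females. LGALS1, which encodes galectin-1, averaged 1696 ± 245 scaled CPM in females and 99.9 ± 4.60 in males, with an adjusted p of 1.00e-06. GAPDH differed by 2.62. PAG17 had 5474 ± 529 scaled CPM in females and 808 ± 36.9 in males, and CSH2 had 899 ± 134 against 198 ± 65.4. The calls of PAG17 and CSH2 were lost when all 12 libraries of the day were fitted together. Of the 21 pregnancy-associated glycoproteins, 19 were higher and 1 lower on both counts, with a median of 2.28 and an adjusted p of 1.14e-05. All 10 placental lactogen and prolactin-related genes were higher on both counts, with a median of 2.21 and an adjusted p of 0.00477. Of 21 glycolysis genes, 15 were higher and 2 lower over all genes and when adjusted over the list alone, with an adjusted p of 0.00477. Of the 25 methylation genes, 15 were lower and 4 higher on both counts, with an adjusted p of 0.0453. That call was lost without female AI replicate 2 (0.0727) or male AI replicate 1 (0.0563). The last 4 lists had an adjusted p = 0.443 with an estimated correlation. All 74 ribosomal protein genes and all 13 mitochondrially encoded genes were higher on both counts, with medians of 1.91 and 3.25, and their calls were lost at an adjusted p = 0.555 with an estimated correlation. Of the 74 nuclear oxidative phosphorylation genes 70 were higher on both counts, with an adjusted p = 0.550 with an estimated correlation.

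After IVP on day 18, limma called 5499 of 10986 genes, 2557 higher and 2942 lower in females, in RPKM. APOA2 averaged 156 ± 47.4 RPKM in females and 1.24 ± 0.318 in males. APOA1 had 2173 ± 435 against 261 ± 83.3 RPKM. The linker histone gene H1-2 lay at 1.29 ± 0.740 RPKM in females and 386 ± 178 in males, and the maintenance methyltransferase DNMT1 at 2.28 ± 0.4997 against 13.3 ± 4.11. Of 18 endoderm genes, 7 were higher and 2 lower over all genes, and 9 and 2 when adjusted over the list alone, with an adjusted p of 0.0418. The endoderm call was lost without female IVP replicate 2 (0.0521) or male IVP replicate 3 (0.0564). Of the 25 methylation genes, 12 were lower on both counts, with an adjusted p of 0.0153. Both calls were lost at an adjusted p = 0.728 with an estimated correlation. Of 75 ribosomal protein genes 72 were higher over all genes and 73 when adjusted over the list alone, with an adjusted p = 0.743 with an estimated correlation. All 13 mitochondrially encoded genes were higher on both counts, with a median of 5.20 and an adjusted p = 0.749 with an estimated correlation.

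After IVP on day 32, limma called 6237 of 13356 genes, 2990 higher and 3247 lower in females. Globin genes were among the highest. HBG averaged 315 ± 383 RPKM in females and 1.24 ± 1.79 in males, and HBE1 7422 ± 6595 against 440 ± 562. Of 22 erythroid genes, 8 were higher over all genes and 6 when adjusted over the list alone, with an adjusted p of 0.0179. The list call was lost without female IVP replicate 1 (0.0699), whose erythroid genes were higher by 3.28 than in the other female day 32 libraries, and without male IVP replicate 1 (0.0579). Without female IVP replicate 1 the HBG difference went from 6.68 to 5.68 and stayed called. The HBE1 call was lost without male IVP replicate 1 (0.0570) or male IVP replicate 2 (0.0591). All 75 ribosomal protein genes and 12 of the 13 mitochondrially encoded genes were higher on both counts, with medians of 2.69 and 3.04. These 3 lists had an adjusted p = 0.978 with an estimated correlation. Of 35 antioxidant genes, 14 were higher on both counts, among them PRDX1 at 366 ± 82.9 against 72.9 ± 16.0 RPKM, with an adjusted p of 0.00117 for the list and adjusted p = 0.445 with an estimated correlation. The number of genes called was 3553 without male IVP replicate 2, 3582 without male IVP replicate 3 and 3820 without male IVP replicate 1. Without female IVP replicate 1 it was 7566.

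Histone genes gave the widest separation by sex. Of the replication-dependent histone genes, 43 of 43 were called higher in males after AI on day 18, 42 of 42 after AI on day 32, 42 of 43 after IVP on day 18 and 42 of 42 after IVP on day 32. Their medians were -5.08, -4.63, -5.48 and -5.17. The medians of the replacement histone variants were 0.53, 0.59, 0.39 and 0.77, and 0 of them were called higher in males. The AI and IVP sex comparisons of day 18 shared 2224 genes higher in females, where independent lists of these sizes would share 776, and 2615 lower, where they would share 878. On day 32 they shared 2693 higher and 2699 lower, against 1089 and 906 for independent lists. The AI values were scaled CPM and the IVP values RPKM. Female and male libraries differed in composition in every group, so both comparisons hold that difference. The shared counts are therefore no independent support for an effect of sex.

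**Figure D4:**
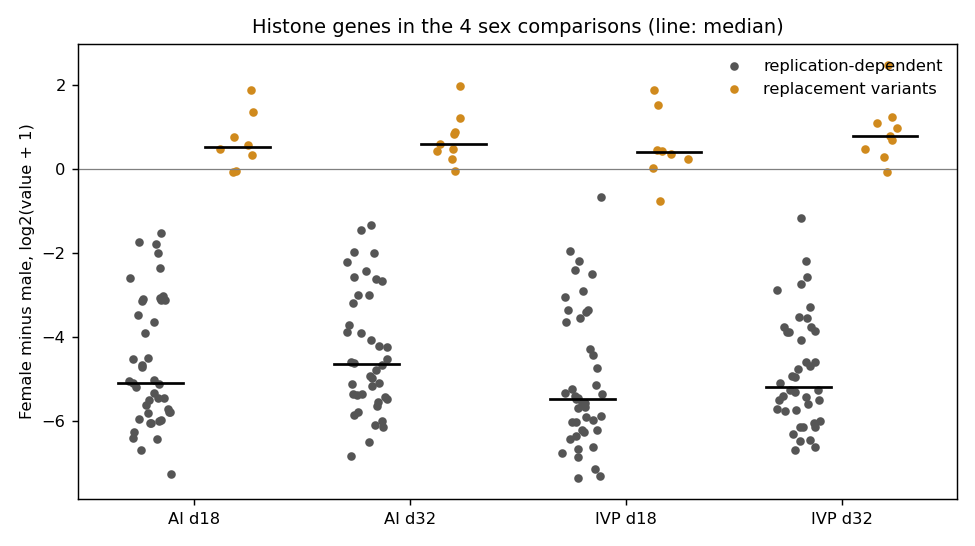
Log2 difference, female minus male, of replication-dependent histone genes (grey) and replacement histone variants (orange) in the 4 sex comparisons, with a point for each gene and a line for each median. The replication-dependent genes had medians between -5.48 and -4.63, and the replacement variants between 0.39 and 0.77.

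The last question was how the membranes differed between days 18 and 32, with AI and IVP groups weighted equally. In females limma called 6281 of 12451 genes, 3349 higher and 2932 lower on day 32. In males it called 8335 of 13512 genes, 4245 higher and 4090 lower. The sexes shared 2561 genes that were higher on day 32 and 2265 that were lower, where independent lists would share 958 and 913. Day also parted the kind of tissue, since a piece of conceptus was taken on day 18 and of chorioallantois on day 32.

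In females the collagen gene COL3A1 changed by 11.72, from 0.0909 ± 0.0815 scaled CPM in AI day 18 libraries to 4484 ± 1943 in AI day 32 libraries. In the female IVP libraries it went from 1.79 ± 2.47 to 18382 ± 27870, a mean that female IVP day 32 replicate 1 carried with 58190 CPM against 4590 in the other female day 32 libraries. The change was 10.97 without that library. PRP1 changed by 9.67 in females and 10.16 in males, and PAG17 by 8.73 and 8.90. IGF2 rose by 6.01 in females and 7.19 in males, and its male AI groups averaged 10.9 ± 6.46 and 1189 ± 514 scaled CPM on days 18 and 32. The imprinted growth suppressor PHLDA2 rose by 6.94 in males. The Kunitz-type trophoblast protein gene TKDP1 changed by -11.55 in females and -10.95 in males, from 32592 ± 3723 to 13.6 ± 15.4 scaled CPM in the female AI groups. The pluripotency factor LIN28A changed by -5.81 in males and the polyamine enzyme ODC1 by -5.09 in females.

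In females 13 of 17 pregnancy-associated glycoproteins were higher on day 32 over all genes and when adjusted over the list alone, with a median of 5.91 and an adjusted p of 6.64e-04. All 6 placental lactogen and prolactin-related genes were higher on both counts, with a median of 7.94. Of 21 mesenchyme genes 17 were higher and 1 lower over all genes, and 17 and 2 when adjusted over the list alone. For endothelium 8 of 10 genes were higher and 1 lower, and 9 and 1 when adjusted over the list alone. For erythroid cells 6 of 7 were higher on both counts. Of 22 interferon-stimulated genes 16 were higher on both counts, with a median of 1.81. Of 26 imprinted genes 15 were higher and 3 lower, and 16 and 3 when adjusted over the list alone. Ribosomal protein genes moved the other way, with 63 of 75 lower over all genes and 65 when adjusted over the list alone, and so did 19 of 40 cell cycle genes on both counts, of which 4 were higher. The glycoprotein list had an adjusted p = 0.535 with an estimated correlation, and the other 8 lists an adjusted p = 0.419 with an estimated correlation.

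In males 16 of 18 pregnancy-associated glycoproteins were higher on day 32 on both counts, with a median of 6.29, and so were all 6 placental lactogen and prolactin-related genes. Of 29 imprinted genes 19 were higher and 3 lower, and of 40 cell cycle genes 33 were lower and 4 higher, both over all genes and when adjusted over the list alone. These 4 lists had an adjusted p = 0.395 with an estimated correlation. Of 22 mesenchyme genes 19 were higher and 2 lower on both counts, and of 13 endothelium genes 12 were higher. Of 28 interferon-stimulated genes 22 were higher and 1 lower over all genes, and 22 and 2 when adjusted over the list alone. Of 24 cholesterol biosynthesis genes 18 were lower and 1 higher on both counts, with a median of -1.36. The last 4 lists had an adjusted p = 0.522 with an estimated correlation. Of 74 ribosomal protein genes 56 were lower over all genes and 59 when adjusted over the list alone, with a median of -0.77 and an adjusted p = 0.531 with an estimated correlation.

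**Figure D5:**
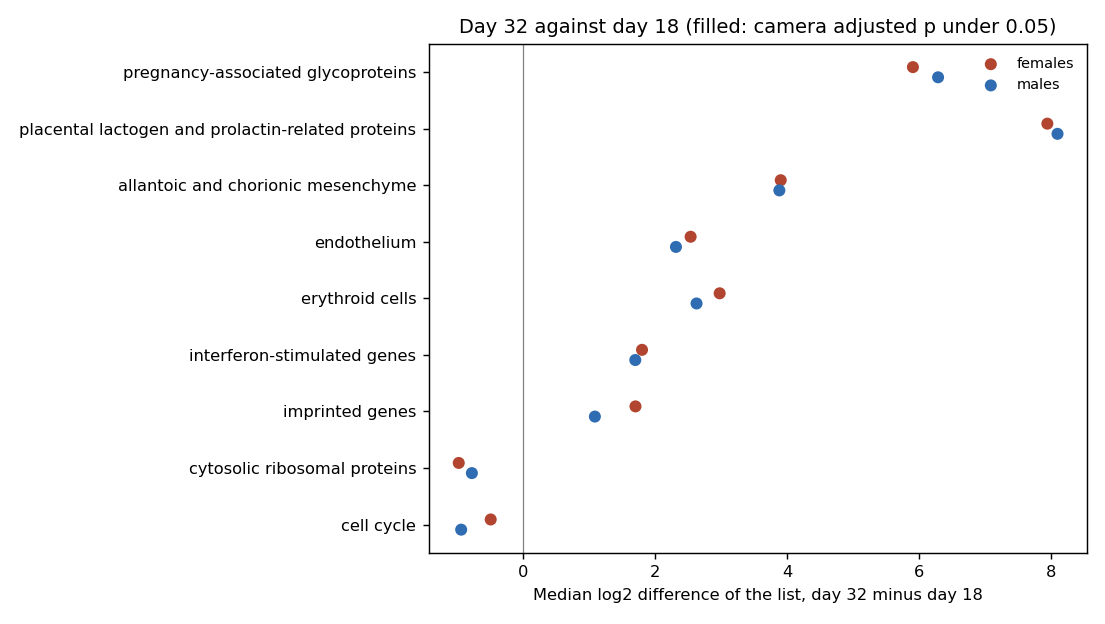
Median log2 difference of 9 gene lists, day 32 minus day 18, in females and in males (filled points have a camera adjusted p under 0.05 at the preset correlation). Placental lactogen and prolactin-related genes had medians of 7.94 and 8.10, and ribosomal protein genes of -0.97 and -0.77.

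Of the list calls that camera made at its preset correlation, none in the 12 comparisons held with an estimated correlation. In the 4 method comparisons camera called 3, 15, 4 and 11 lists, and other splits of the same 6 libraries gave up to 9, 19, 13 and 18. The rotation test fry asks whether the genes of a list move on balance in 1 direction, without comparing them with other genes. It called 0 lists in the 4 method comparisons and in both interactions. It called 15 and 19 lists in the AI sex comparisons of days 18 and 32, and 10 and 6 in those of IVP. In the day comparisons it called 26 lists in females and 23 in males.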

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

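The tests in this part were chosen only after the results were seen, except for the interactions, the gene lists, the splits of the libraries and the test of small nucleolar RNAs.

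The method effect differed between the sexes in 20 list calls by camera at its preset correlation, in a test of the difference itself. Of these calls 11 were on day 18 and 9 on day 32, and some lists were called on both days. Each value is the median over a list of male IVP minus male AI less female IVP minus female AI, on the log2 scale. On day 18 the medians were 0.99 for pregnancy-associated glycoproteins, -1.14 for mesenchyme, -1.25 for endoderm and yolk sac and -1.23 for endothelium. Imprinted genes had -0.49, nuclear oxidative phosphorylation genes -0.44, mitochondrially encoded genes -1.03 and ribosomal protein genes -0.64. The unfolded protein response had 0.53, antioxidant defence -0.053 and extracellular matrix -0.76. On day 32 the medians were 2.11 for pregnancy-associated glycoproteins, 1.51 for placental lactogen and prolactin-related proteins, -1.38 for endoderm and yolk sac, -1.09 for endothelium and -1.80 for erythroid cells. Leukocyte genes had -0.96, nuclear oxidative phosphorylation genes -0.44, ribosomal protein genes -0.87 and antioxidant defence -0.31. With an estimated correlation the adjusted p-values were 0.0570 to 0.653 on day 18 and 0.617 to 0.941 on day 32, so none of these calls held. With each library left out in turn, 4 of the 11 day 18 lists and 3 of the 9 day 32 lists were called in every fit. Without female IVP day 32 replicate 1, the day 32 medians were -0.009 for pregnancy-associated glycoproteins, -0.42 for placental lactogen and prolactin-related proteins, -0.78 for endoderm and yolk sac and -1.12 for erythroid cells, and 3 of the 9 lists were called. The medians were -0.56 for endothelium and -0.11 for antioxidant defence in that fit. The endoderm median was -0.27 without male AI day 32 replicate 2. Without female IVP day 32 replicate 2, oxidative phosphorylation genes had -0.23 and antioxidant defence -0.52. On day 18 without male AI replicate 3, mesenchyme had -0.08, endothelium -0.54, imprinted genes -0.23 and extracellular matrix -0.27. Without male IVP replicate 1, oxidative phosphorylation genes had -0.11 and ribosomal protein genes -0.31. Pregnancy-associated glycoproteins had 0.39 without female AI replicate 3 and 1.86 without female IVP replicate 3. Mitochondrially encoded genes had -0.17 and the unfolded protein response 0.33 without female IVP replicate 1, and antioxidant defence 0.05 without female IVP replicate 2. Of 100 drawn splits of the 12 day 18 libraries, 13 called as many lists as the 11 of the real split, and the highest other split called 19. On day 32, 81 of 100 splits called as many as the 9 of the real split, with 21 as the highest. Chance cannot be excluded for either count.

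Between 5499 and 9239 genes differed between female and male libraries, and this pattern was weighed against the make-up of the libraries. Removing a smooth trend on gene length left 68.2% or more of the limma calls with their sign in each of the 4 comparisons, which argues against length bias as the whole cause. The median of replication-dependent histone genes, whose transcripts mostly lack poly(A) tails, lay below that of the replacement variants by a log2 difference of -5.22 or further from 0 in each comparison. That is what male libraries holding transcripts without such tails, and female libraries lacking them, may show. Small nucleolar RNA genes did not give the advance prediction of over 75% of their scaled reads in male libraries, since the male shares were 59.0% (SD over 9 pairings 12.4) and 61.9% (SD 3.2) after AI on days 18 and 32, and 60.7% (SD 14.4) and 66.0% (SD 8.0) after IVP. The advance bound against that source was a share under 60% in any comparison. The 59.0% after AI on day 18 lay under it, so by that bound the test argues against the source. It lay under by less than its SD of 12.4, a spread that the bound did not allow for. With that spread the test cannot decide. The sex of the conceptus stays open as untested, because sex and library make-up cannot be told apart in this design, and the highest of the 4 medians of X-linked genes with a Y homologue was -0.08 with the length trend removed.

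The gene lists called lower after IVP in males on day 32 were weighed next, for ribosomal proteins, oxidative phosphorylation, cholesterol biosynthesis and the unfolded protein response. With the gene length bias removed as a smooth trend, 4 of the 4 lists were still called lower, and the ribosomal median went from -0.39 to -0.30. The oxidative phosphorylation median went from -0.22 to -0.14. Male IVP day 32 replicate 2 had the most vimentin (VIM) of the male day 32 libraries at 1440 CPM, and a test of more mesenchyme in IVP replicate 2 as the cause left 4 of 4 lists lower without that library, while the mesenchyme median went from 0.76 to 0.31. The tests argue against length bias, and against replicate 2 alone, as the whole cause of these calls. Mesenchyme genes were still called higher without replicate 2, at an adjusted p of 0.0402 in camera. More mesenchyme in the other IVP libraries was therefore not excluded. Both tests rest on the 4 list calls of camera at its preset correlation. All 4 calls were lost with an estimated correlation, and 5 of the 10 splits of the 6 libraries called as many lists as the real 11, the highest other 18, in too few splits for a share under 0.05. An effect of the method on male conceptuses remains an untested possibility, and so does whatever the R number of the titles stands for, which differs between the methods.

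Replicate 1 of female IVP on day 32 stood apart from the other female day 32 libraries. A day 18 library under a day 32 label is argued against by 3 of 3 genes that lay nearer to the day 32 libraries, with VIM at 2458 CPM against 413 in the other female day 32 libraries and 1.90 on day 18. Low depth is argued against by 0 of the 6 day 32 libraries with fewer reads having glycoproteins as low. Those 6 were all male, so no female day 32 library of lower depth could be compared. Replicate 1 had the fewest reads of the female day 32 libraries at 49372358. The median of its pregnancy-associated glycoproteins differed by -6.93, that of trophoblast identity genes by -1.84 (SD of members 2.34), that of leukocyte genes by 0.96 (SD of members 1.07) and that of endoderm genes by 3.35 (SD 1.65). A smaller share of trophoblast alone would raise other cell types alike. The leukocyte and endoderm medians lay further apart than either SD, which by the bound used argues against it. Adding 1 before log2 shrinks rises of genes with low values, however, and the leukocyte list held 9 genes. The test therefore cannot decide on a smaller share of trophoblast. A piece richer in endoderm, mesenchyme and erythroid cells may remain as well. Such a richer piece was not tested as an explanation for this library, nor was any further one.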

How the results depend on the processing

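The splits and the alternatives of the plan were set before the data were examined, whereas the edgeR test with TMM factors, the removal of a length trend, the fits without doubted female IVP libraries and the repeats of the list tests without single libraries were tests chosen after the results were seen. No paired analysis was possible because the labels do not say which libraries of different groups belong together.

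For IVP against AI in females on day 18, limma called 1 gene, edgeR with RLE or TMM factors 0, DESeq2 75 and the fit of all 12 libraries 0. In females on day 32 the call count went from 0 to 72 with DESeq2 and to 115 with DESeq2 without IVP replicate 1, and in males on day 18 from 0 to 4. In males on day 32 the count of 4 became 107 with the stricter filter, 2 with either edgeR setting, 1285 with DESeq2 and 1 in the fit of all 12 libraries, where 0 were lower. The interactions went from 0 to 18 and 47 genes with DESeq2 on days 18 and 32. The cause of these differences was not tested. Removing the length trend left 3 genes in males on day 32, and 6483, 8812, 4494 and 5281 genes in the sex comparisons. The R number as a covariate gave 6605 and 9067 genes in the AI sex comparisons. Without both doubted libraries, IVP day 18 replicate 1 and IVP day 32 replicate 1, 6929 genes were called between days in females. That fit kept IVP day 32 replicate 3, whose description named AI.

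Of the 35 lists, camera called 3, 15, 4 and 11 in the method comparisons, 7 and 9 in the AI and 6 and 5 in the IVP sex comparisons, 11 and 9 in the interactions and 17 and 14 between days. An estimated correlation gave 0 in all 12. The fry test gave 0 in the method comparisons and interactions, 15 and 19 in the AI and 10 in the IVP day 18 sex comparison, and 26 and 23 between days in females and males.

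With each library left out in turn, the genes called ranged from 0 to 4 in females on day 18 and from 0 to 5 in males on day 32. They were 0 in every such fit for females on day 32 and for males on day 18. They ranged from 3553 to 7566 for sex after IVP on day 32, where the lowest was without male IVP replicate 2 and the highest without female IVP replicate 1, and from 0 to 1 for the day 18 interaction, where the highest was without male AI replicate 1. The lists called ranged from 4 to 11 in females and 3 to 9 in males on day 18, from 4 to 10 for sex after IVP on day 32 and from 6 to 19 for the day 32 interaction. Over single genes, 3895 of 3931 settings of called genes kept the call and 36 lost it, and 62 of 1473 settings of uncalled genes gained one. For called lists described in the text, 544 of 645 settings kept the call and 101 lost it. Some list medians changed sign without 1 library, as mesenchyme in females on day 32 did, from 0.70 to -0.38 without IVP replicate 1.

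The splits of the 6 libraries into 3 and 3 number 10 with the real one included. That is too few for a share under 0.05, so no share is judged. The real count, the splits that reached it (the real one among them) and the highest other split are given. For genes, 3 splits called as many as the real 1 in females on day 18, with 2 as the highest other. For females on day 32 all 10 called as many as the real 0 and the highest other was 0, and for males on day 18 all 10 did and the highest other was 1. For males on day 32 the real 4 was the only such split (1) and the highest other was 0. The sex comparisons had 7137, 9239, 5499 and 6237 genes, each the only such split (1), against 0 in the highest other. For lists, 8 splits called as many as the real 3 in females on day 18 (highest other 9), 6 as the real 15 on day 32 (19), 10 as the real 4 in males on day 18 (13) and 5 as the real 11 on day 32 (18). For the sex comparisons, 6 splits reached the real 7 (highest other 14), 7 the real 9 (14), 6 the real 6 (13) and 10 the real 5 (23).

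For the interactions, the real count of 0 genes was reached by all 100 drawn splits on both days, as it must be, so the splits say nothing on these counts (highest others 5 and 0). For day, 1 of 100 splits reached the real 6281 genes in females (highest other 2177) and 1 of 100 the real 8335 in males (2673), so chance can be excluded for these counts. The drawn splits exchanged days within each method, so some can keep most of the real day labels. The splits that called 2177 or 2673 genes may thus carry part of the day difference, which was not tested. For the lists between days, 12 of 100 splits reached the real 17 in females (highest other 19) and 34 the real 14 in males (20), so chance cannot be excluded for either.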

Other observations

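The values in this part were picked out after the data were seen, and no tests beyond the planned ones were made on them, except the counts shared between comparisons.

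COX7C separated female libraries by method on both days, apart from 1 library. In the male groups, after AI as after IVP, it averaged 0.625 to 1.38 CPM, so low values were not particular to IVP libraries. It had 15.3 to 17.9 CPM in the female AI day 32 libraries, and 0.405 and 0.319 CPM in female IVP day 32 replicates 1 and 2, while replicate 3 had 16.3 CPM. PRUNE2, which fell after IVP in males on day 32, had 5.03 to 12.6 CPM in the female AI day 32 libraries and 0.0405 and 0.256 CPM in female IVP replicates 1 and 2, while replicate 3 had 12.7 CPM. MFSD1 had 27.1 and 47.6 CPM in replicates 1 and 2 and 80.6 CPM in replicate 3, against 74.9 to 113 CPM in the AI libraries. Some genes that DESeq2 called in females on day 32 set replicate 3 apart from the AI libraries. CYP17A1 had 1.31 CPM in it and 4.39 to 10.8 CPM in the AI libraries. FETUB had 580 CPM in it, 12.5 to 26.5 CPM in the AI libraries and 23.6 CPM in IVP replicate 2. These genes were picked from calls that counted replicate 3 as IVP, so they cannot decide its label. The description of replicate 3 named AI, while its title, its characteristics and its table columns named IVP. The label was kept as IVP in every comparison.

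The DESeq2 calls of the method comparisons in females and males on day 32 come from separate libraries. They shared 2 genes higher after IVP and 1 lower, where independent lists would share 1 and 1, and the Spearman correlation of the 2 sets of changes across genes was 0.396. Genes are not independent replicates, so this correlation carries no p-value.

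Day brought the same direction in both sexes for most genes called in both, with 33 genes higher in females and lower in males on day 32, and 19 the other way round, against 2561 and 2265 in the same direction. Interferon-stimulated genes had medians of 1.81 in females and 1.70 in males between days, in tables where interferon tau genes were listed only for day 18. Over all genes, 16 of 22 were higher on day 32 in females, and 22 of 28 were higher and 1 lower in males. Adjusted over the list alone, 16 were higher in females, and 22 were higher and 2 lower in males. The list calls were lost, at an adjusted p = 0.419 with an estimated correlation in females and an adjusted p = 0.522 with an estimated correlation in males.

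SRGN, which encodes a granule proteoglycan, was 226 ± 347 scaled CPM in female AI day 18 libraries and 1.45 ± 1.16 in male ones. It rose by 9.06 between days in males. PGF and SRGN had wide spreads in the female AI day 18 group, where the SD exceeded the mean for both.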
